A study of Homo sapiens with 49 samples.

How the data were processed

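The data are 49 files of gene counts, 1 per library, of astrocytes from human cerebral cortex. Per the labels' protocols, total RNA was extracted with a column kit, converted to double-stranded cDNA with an amplifying kit (Ovation RNA-seq V2) and made into Illumina libraries with 10 cycles of PCR. How the astrocytes were purified is not given in the sources used here. The deposited values are raw counts of reads per gene, and the submitters' processing notes name STAR, HTSeq, edgeR, limma and the genome build GRCh38, without versions or settings. The annotation release, the strand setting and any read filter are not given in the sources used here. The counts are not normalized. Because strand is not stated, reads of a gene and of an overlapping antisense gene cannot be told apart.

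Each file holds 58302 gene rows and 5 summary rows of the counting program. The summary rows stayed out of library sizes and tests. Alignments to several places were 30.8% to 74.2% of all entries, and reads in no gene were 3.19% to 27.4%, and ambiguous reads were 0.518% to 1.87%. Gene identifiers were matched to GENCODE release 29, which gave 58039 of them (99.5%) a name and coordinates on GRCh38. The 263 unmatched identifiers held at most 0.0426% of a library's counts and were left out. A further 519 genes (those of chromosome Y, XIST and TSIX) were left out of all tests because the samples are human, which left 57520 genes. Library totals and shares of counts were taken over all 58302 gene rows, and the totals were 3784867 to 24911905 counts. No 2 of the 1176 pairs of libraries held identical values, and the lowest chi-square per degree of freedom between 2 libraries was 10.8, so none was counted as a repeat.

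Groups were taken from the labels. The main test was edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with the groups, libraries were scaled by TMM, and a quasi-likelihood model with group and sequencing batch as terms was fitted to all 49 libraries with robust dispersion. This left 17932 genes, which held at least 99.2% of each library's counts, and 43 residual degrees of freedom. The common biological coefficient of variation was 0.474. Adjusted p values are Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of its F statistic. CPM values use TMM-scaled totals, and log2 CPM values use a prior count of 2. On counts simulated from the real means over 17932 genes, the test recovered 36.4%, 65.7% and 91.1% of genes changed by 1, 2 and 3 on the log2 scale for peritumor against control. For epilepsy against control it recovered 59.4%, 88.6% and 91.8%, and for peritumor against epilepsy 44.1%, 70.4% and 95.1%. The simulated genes varied independently of one another apart from batch. No library held a shift shared by many genes, so recovery in the real libraries may differ.

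Before the data were examined, 33 gene lists with 539 entries were fixed (astrocyte functions, stress and metabolic pathways, glioma-associated genes and markers of other cell types). The 31 lists with at least 3 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists. All list calls were lost with an estimated correlation, and fry called 11, 0 and 13 lists for peritumor against control, epilepsy against control and peritumor against epilepsy. Named genes follow a rule fixed at the same time. It takes the 8 highest and 8 lowest log2 fold changes among called protein-coding genes with a mean of at least 2 CPM and the same direction in batches 2 and 4. It adds the 3 members of smallest p of each called list or list with at least 3 called members. Where fewer than 4 genes came from the first part, the 6 protein-coding genes of smallest p were added. AQP4, GFAP, ALDH1L1, SLC1A2, P2RY12, MBP, SNAP25 and CLDN5 were always included. Results for some genes under this rule are not reported here.

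Library measures were compared with two-sided exact permutation tests. Alternatives were RLE scaling, no filter, no batch term, only the groups compared, each of batches 2 and 4 alone, scores of microglia, oligodendrocytes, neurons and endothelium as covariates, DESeq2 1.42.0, limma voom with quality weights, camera with estimated correlation, fry, and leaving out each peritumor or control library. Leaving out shallow libraries was to be tried too, but no library was under the limit set for it. Within a batch, the alternatives filtered genes anew, while the batch values printed beside pooled ones used the 17932 genes. Removing the 3 libraries above 60 on the second principal component, and mitochondrial rRNA percent as a covariate, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.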

Results

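RNA was sequenced from astrocytes of human cerebral cortex, the glial cells that take up glutamate, buffer potassium and are coupled by gap junctions. The 49 libraries fall into 3 groups by the tissue they came from: control cortex (12 libraries), epileptic cortex (31 libraries) and cortex around a tumour (6 libraries, called peritumor here). The series addresses how astrocyte expression differs with the tissue setting, and the comparison of the groups was made in 3 pairs. The labels do not say that libraries of a group came from separate donors, so every p-value measures the spread between these libraries. Libraries held 3784867 to 24911905 counts over all 58302 gene rows, with a median of 7766081. Depth followed the sequencing batch given in the labels, with a median of 5334710 in batch 2 (8 control, 8 epilepsy and 3 peritumor libraries) and 17057400 in batch 4 (3 control, 17 epilepsy and 2 peritumor libraries). Batch 3 held 1 control, 3 epilepsy and 1 peritumor library, and batch 1 held 3 epilepsy libraries only, so within-batch values were computed in batches 2 and 4.

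Astrocyte markers had the highest mean of the cell type lists in every group, though not in every library. Their mean was 9.93 ± 0.31 log2 CPM (counts scaled to a common library total) in control (SD, n = 12), 9.72 ± 0.71 in epilepsy (SD, n = 31) and 8.66 ± 1.29 in peritumor libraries (SD, n = 6). Oligodendrocyte markers, genes of the cells that make myelin, were at 5.64 ± 1.60, 5.05 ± 1.34 and 7.15 ± 2.02, and markers of their precursors at 4.40 ± 1.53, 5.54 ± 1.39 and 5.75 ± 1.02. Microglia markers were at 3.27 ± 1.53, 4.08 ± 1.28 and 4.50 ± 1.42, neuron markers at 2.09 ± 0.60, 1.89 ± 0.64 and 1.84 ± 0.73, and endothelial markers at 0.79 ± 1.23, 1.19 ± 0.84 and 2.03 ± 1.00. Oligodendrocyte markers lay above astrocyte markers in peritumor replicate 1, at 9.39 against 9.20 log2 CPM. Precursor markers lay above them in peritumor replicate 6, at 7.173 against 6.201 log2 CPM. None of the 11 T cell markers passed the filter on low counts, and 1 of the 8 erythrocyte genes did, so neither list was tested. Mitochondrial ribosomal RNA, a part of each library that varies with RNA quality and preparation, took 21.04% to 64.3% of counts. It averaged 46.5% ± 13.3 in peritumor (SD, n = 6), 34.5% ± 8.86 in control (SD, n = 12) and 36.8% ± 10.3 in epilepsy libraries (SD, n = 31). The difference between peritumor and control had p = 0.0343 in a two-sided exact permutation test (adjusted p = 0.218 over 16 tests of library measures), and that between peritumor and epilepsy had p = 0.0497 in the same exact test (adjusted p = 0.218). These tests permuted labels across batches, and the mean share was 40.3% in batch 2 and 34.9% in batch 4. Within batch 2 the exact permutation p was 0.0364 for 3 peritumor against 8 control libraries (adjusted p = 0.218). After batch means were removed, 3 libraries (2 peritumor and 1 epilepsy) lay at 80.5 to 141.4 on the second principal component, and the other 46 lay between -45.5 and 34.6. Glioma-associated genes averaged 5.167 to 6.705 log2 CPM in these 3 libraries, against 2.822 to 5.35 in the other 46. Cell cycle genes averaged 1.716 to 4.6, against -0.344 to 3.487. Peritumor replicate 6 and epilepsy replicate 31, both among the 3, had the lowest astrocyte marker means of their groups (6.201 and 6.973). What sets the 3 libraries apart was not tested.

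**Figure D1:**
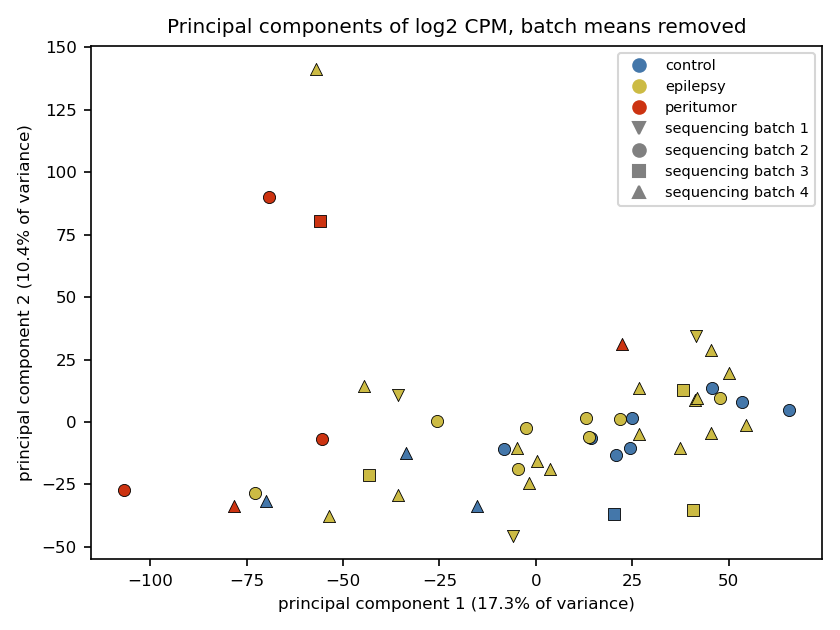
First and second principal components of log2 CPM after removal of batch means, 1 point per library, with colour for the group and shape for the sequencing batch. The components hold 17.3% and 10.4% of the variance, and 3 libraries lie above 60 on the second component.

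Against control, peritumor libraries held more transcripts of cytosolic ribosomal proteins and lower levels of some astrocyte markers, among them the gap junction gene GJA1. All 43 ribosomal protein genes had a positive log2 fold change, with a mean of 0.74 ± 0.24 (SD over genes), and 27 of them rose. RPS19, a protein of the small ribosomal subunit (ENSG00000105372, chromosome 19, 41859918 to 41872926), rose by 1.34 ± 0.25 on the log2 scale (SE, adjusted p = 0.00223), from 29.8 ± 11.7 CPM in control (SD, n = 12) to 77.4 ± 26.2 CPM in peritumor (SD, n = 6). RPL30 (1.12) and RPS13 (1.01) rose as well, and all 6 peritumor libraries lay above the control median for each of the 3 genes. With mitochondrial rRNA percent as a covariate the 3 calls were lost (adjusted p from 0.0503 to 0.0543), at 0.94, 0.90 and 0.73 in the order named. Ribosomal protein genes share sequence with many processed pseudogenes, so their counts are uncertain where reads could be split. The list changed by a mean of 0.72 within batch 2 and 0.70 within batch 4 (camera adjusted p = 3.7e-24, 36 members higher adjusted over the list alone). Its adjusted p was 0.365 with an estimated correlation between genes. In batch 4 its mean log2 CPM was 6.18 in peritumor replicate 4 and 7.01 in replicate 5, against 5.98 to 6.02 in the 3 control libraries. The batch 4 value thus rests mostly on replicate 5.

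Of 23 astrocyte markers, 5 fell, 1 rose and 17 did not pass, with a mean log2 fold change of -0.85 ± 0.68 (SD over genes). The gene that rose was S100B, named after its values were seen, at 0.98 ± 0.31 (SE, adjusted p = 0.0403), with 1.65 within batch 2 and 0.032 within batch 4. Oligodendrocytes also express it. GJA1, the gap junction protein connexin 43 (ENSG00000152661, chromosome 6, 121435577 to 121449727), changed by -1.45 ± 0.36 (SE, adjusted p = 0.0109), from 1547 ± 609.1 CPM in control to 523.9 ± 385.7 CPM in peritumor. It was -0.96 without the 3 libraries that stand apart, and -1.23 with the mitochondrial rRNA covariate, which ended the call (adjusted p = 0.083). ACSBG1, an acyl-CoA synthetase, changed by -1.43 ± 0.35 (adjusted p = 0.00935), and its call was lost without the libraries that stand apart (-0.93, adjusted p = 0.0542) and with that covariate (-1.31, adjusted p = 0.0648). Within batch 4 GJA1 had -0.84 and ACSBG1 -0.56. FGFR3 changed by -1.55 ± 0.41 (adjusted p = 0.0172), with -0.75 within batch 4, and its call was lost without peritumor replicate 3 (adjusted p = 0.0683). The list of glutamate, GABA, potassium and water handling had 4 of 18 members lower and none higher, with a mean of -0.81, and it shares several genes with the astrocyte markers. SLC1A2, the main glial glutamate transporter, had a log2 fold change of -1.44 ± 0.48 and an adjusted p of 0.0523. AQP4, the astrocyte water channel, had -0.55 ± 0.30 (adjusted p = 0.242), ALDH1L1 had -0.29 ± 0.37 (adjusted p = 0.662) and the filament protein GFAP had 0.99 ± 0.49 (adjusted p = 0.189). The 2 lists had camera adjusted p values of 1.2e-10 and 5.6e-09, and an adjusted p of 0.365 each with an estimated correlation. Their means were -0.79 and -0.74 within batch 2 and -0.28 and -0.35 within batch 4, where neither was called, and -0.52 and -0.53 without the 3 libraries that stand apart. Adjusted over the list alone, 17 astrocyte markers and 13 members of the handling list were lower, and 1 astrocyte marker was higher.

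Reactive astrocyte genes rose as a list, with a mean of 1.19, though 3 of 23 members passed by themselves and 6 were higher adjusted over the list alone. TIMP1, an inhibitor of matrix proteases, rose by 1.87 ± 0.43 (SE, adjusted p = 0.00764). S100A10 rose by 3.69 ± 0.86 (adjusted p = 0.00769), and its call was lost without peritumor replicate 3 (adjusted p = 0.082), without the libraries that stand apart (2.42) and with the mitochondrial rRNA covariate (2.10). NES, an intermediate filament protein of progenitor and reactive cells, rose by 2.72 ± 0.77 (adjusted p = 0.0245), and its call was lost without peritumor replicate 3 or 6 (adjusted p up to 0.15) and with mitochondrial rRNA percent as a covariate (1.05, adjusted p = 0.4975). The list had a camera adjusted p of 0.00267 and an adjusted p of 0.455 with an estimated correlation. Its mean was 1.07 within batch 2 and 1.39 within batch 4, and 0.57 with mitochondrial rRNA percent as a covariate, which ended the call (adjusted p = 0.0513). In batch 4 its mean log2 CPM was 4.26 in peritumor replicate 4 and 5.81 in replicate 5, against 3.71 to 4.43 in control. That batch value thus rests on replicate 5.

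Cell cycle genes rose with a mean of 2.00, and 3 of 19 passed, including MCM5 (1.12 ± 0.29, adjusted p = 0.0155) and MCM2 (1.62 ± 0.44, adjusted p = 0.0171), both parts of the helicase that opens replication origins. The call of MCM5 was lost without peritumor replicate 1 or 6 (adjusted p up to 0.141), and that of MCM2 without replicate 1, 3 or 6 (adjusted p up to 0.0813). Within batch 4 they had 0.039 and 0.99. Adjusted over the list alone, 9 cell cycle genes were higher. The mean was 2.48 within batch 2 and -0.19 within batch 4, 1.20 without the 3 libraries that stand apart and 0.71 with mitochondrial rRNA percent as a covariate. Among glioma-associated genes, 4 of 19 rose, and 6 were higher adjusted over the list alone, with a mean of 1.49, at 1.67 within batch 2 and 0.34 within batch 4. That mean was 0.95 without the libraries that stand apart and 0.51 with the mitochondrial rRNA covariate. CDK4, a kinase that drives entry into S phase, rose by 1.33 ± 0.22 (adjusted p = 0.000573), at 1.76 within batch 2 and 0.41 within batch 4, and lay above the control median in 6 of 6 peritumor libraries. DLL3, a Notch ligand, rose by 2.60 ± 0.65 (adjusted p = 0.0122), with 3.62 within batch 2 and -0.37 within batch 4, and its call was lost without peritumor replicate 2 (1.21, adjusted p = 0.221) and with the mitochondrial rRNA covariate (1.26). Both lists had an adjusted p of 0.365 with an estimated correlation (camera adjusted p = 6.3e-07 and 0.00011).

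Markers of other cells also rose as lists: oligodendrocytes (mean 1.72), microglia (1.21), antigen presentation by MHC class II (1.42), endothelium (1.14) and oligodendrocyte precursors (0.68). No more than 1 member of any of these lists passed by itself, and 1, 1, 7, 3 and 0 were higher adjusted over the list alone. Within batch 4 the means were 0.64, -0.08, 0.03, 0.98 and -1.08, against 3.35, 2.12, 2.04, 1.51 and 1.89 within batch 2. CNP, an enzyme of myelin, rose by 1.27 ± 0.39 (adjusted p = 0.0365) and lay above the control median in 4 of 6 libraries. Its call was lost without peritumor replicate 1 or 4 or control replicate 2, 4, 5, 6 or 8 (adjusted p up to 0.214), and its value was 0.82 without peritumor replicate 1 and 0.49 within batch 4. The interferon list rose with a mean of 0.83, at 0.74 within batch 2 and 0.92 within batch 4, with 2 members higher and 3 higher adjusted over the list alone. In batch 4 its mean log2 CPM was 3.03 in peritumor replicate 4 and 4.09 in replicate 5, against 2.83 to 3.09 in control. The hypoxia list fell with a mean of -0.43, at -0.36 within batch 2 and -0.54 within batch 4, with 2 members lower. Adjusted over the list alone, 5 hypoxia genes were lower and 1 was higher. The interferon call was lost without peritumor replicate 1 or 5 (adjusted p up to 0.14), and the precursor call without peritumor replicate 2 or 4 or control replicate 1 or 12 (adjusted p up to 0.0712). With the mitochondrial rRNA covariate both calls were lost, at means of 0.51 (adjusted p = 0.0816) and 0.36 (adjusted p = 0.0871). The precursor call was also lost without the libraries that stand apart (0.54, adjusted p = 0.0791). The cell type covariates ended the calls for precursors and MHC class II (adjusted p = 0.0948 and 0.0797). Those of oligodendrocytes, microglia and endothelium were lost too, as they must be when adjusted for their own scores. Without peritumor replicate 1 the means of microglia and MHC class II were 0.54 and 0.91, and without control replicate 12 that of hypoxia was -0.28. With an estimated correlation, the adjusted p of these 7 lists ran from 0.365 to 0.595. The other 18 lists did not pass, at adjusted p from 0.0606 to 0.878. Among them, 3 members of lipid metabolism and 4 of synapse formation and phagocytosis were lower, and 1 of the latter was higher.

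Across all 17932 genes tested, 1480 passed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 713 higher and 767 lower. More genes were higher than lower with RLE scaling (836 and 693), within batch 2 (1195 and 835) and without the libraries that stand apart (317 and 204). The highest and lowest fold changes that kept their direction in both batches included EYA4, a transcriptional coactivator (ENSG00000112319, chromosome 6, 133240598 to 133532120), at 4.34 ± 0.69 (SE, adjusted p = 0.000573), at 2.90 without peritumor replicate 3 and 2.42 within batch 4. TGFBI, a matrix protein induced by TGF-beta, was at 4.66 ± 0.89 (adjusted p = 0.00239) but at 1.88 without peritumor replicate 5, where its call was lost (adjusted p = 0.131), with 1.61 within batch 2 and 6.15 within batch 4. PAPLN, papilin (ENSG00000100767, chromosome 14, 73237497 to 73274640), was at -2.00 ± 0.39 (adjusted p = 0.00239), and FSTL5 was at -2.54 ± 0.67 (adjusted p = 0.0162), a call lost without peritumor replicate 3 (adjusted p = 0.0593). LTF, lactotransferrin, had the highest value (9.99 ± 2.96), with 52.0 ± 124 CPM over 6 peritumor libraries. It was 4.83 within batch 2, 3.45 within batch 4 and 6.65 without peritumor replicate 6, and its call was lost without peritumor replicate 3 or 6 or control replicate 12 (adjusted p up to 0.153). With the mitochondrial rRNA covariate, CDK4, EYA4, PAPLN and TGFBI alone of the 42 genes called under the naming rule kept their call. Several fold changes stayed about as large with it, such as FSTL5 (-2.23), FGFR3 (-1.34), MCM5 (1.06) and CNP (1.19). For these 4 genes the loss of calls does not show that the mitochondrial rRNA share accounts for them. Others shrank, such as ANXA1 (from 4.63 to 0.78), TOP2A (from 4.64 to 1.19), NES (from 2.72 to 1.05) and CNGA3 (from 4.15 to 2.04). For the genes that shrank, a part of the mitochondrial rRNA share stays open. Without the libraries that stand apart the calls of FGFR3, MCM2, FSTL5 and LTF were lost too (adjusted p from 0.0539 to 0.164), and with the cell type covariates those of MCM2, MCM5 and CNP (adjusted p from 0.0502 to 0.417). CNP is part of the oligodendrocyte score among these covariates, so its loss there says nothing. The count was 56 with mitochondrial rRNA percent as a covariate, all of them among the 1480, and 521 without the 3 libraries that stand apart. It was 375 without peritumor replicate 3, 860 without replicate 1, 661 with the cell type covariates and 0 within batch 4. Of 2088 genes called within batch 2 among the 17932, 65.8% had the same sign within batch 4, against 57.5% of all genes.

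**Figure D2:**
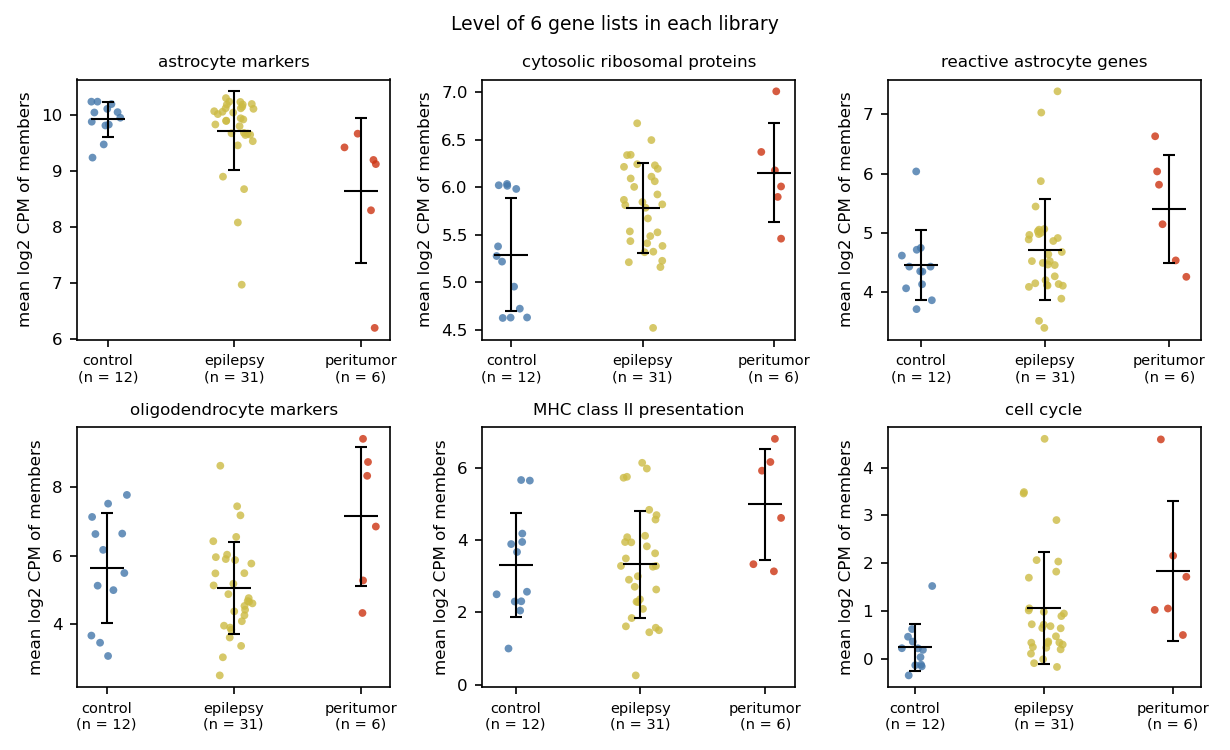
Mean log2 CPM of the members of 6 gene lists in each library, by group, with the mean and SD in black. Peritumor libraries average 8.66 for astrocyte markers and 6.16 for ribosomal proteins, against 9.93 and 5.29 in control, and the groups overlap in each panel.

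Against epilepsy, peritumor libraries showed lower astrocyte markers, higher oligodendrocyte markers and higher MHC class II genes. Of 23 astrocyte markers 14 fell and 1 rose, and of 18 genes of glutamate, GABA, potassium and water handling 13 fell and none rose (means -0.89 and -0.98). GLUL, glutamine synthetase, changed by -1.47 ± 0.38 (SE, adjusted p = 0.00733), from 6232 ± 3772 CPM in epilepsy (SD, n = 31) to 2423 ± 1572 CPM in peritumor (SD, n = 6). The potassium channel KCNJ10 changed by -0.99 ± 0.26 (adjusted p = 0.00769), and none of the 6 peritumor libraries lay above the epilepsy median for either gene. SLC1A2 changed by -1.48 ± 0.44 (adjusted p = 0.021), a call lost without peritumor replicate 3 or 6 (adjusted p up to 0.0713), and was at -0.94 without the libraries that stand apart. Adjusted over the list alone, 18 astrocyte markers and 16 members of the handling list were lower, and 1 astrocyte marker was higher. The list means were -0.76 and -0.99 within batch 2 and -0.57 and -0.53 within batch 4. Their adjusted p was 0.258 each with an estimated correlation (camera adjusted p = 1.7e-11 and 1.3e-11).

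Oligodendrocyte markers rose in 10 of 12 members, with a mean of 2.31, at 2.16 within batch 2 and 2.48 within batch 4. Their mean log2 CPM in batch 4 was 8.72 in peritumor replicate 4 and 4.33 in replicate 5, against 2.52 to 7.17 in epilepsy. That batch value thus rests on replicate 4. MYRF, the transcription factor of myelin genes, rose by 2.75 ± 0.63 (adjusted p = 0.00345), CLDN11 by 2.91 ± 0.68 (adjusted p = 0.00409) and CNP by 1.64 ± 0.33 (adjusted p = 0.00122). MBP, myelin basic protein, had 1.47 ± 0.59 and an adjusted p of 0.0927. MHC class II genes rose in 8 of 10 members, with a mean of 1.89, at 1.93 within batch 2 and 1.41 within batch 4. The batch 4 levels were 5.91 log2 CPM in peritumor replicate 4 and 3.13 in replicate 5, against 0.25 to 5.97 in epilepsy. This value too thus rests mostly on replicate 4. Adjusted over the list alone, 12 oligodendrocyte markers and 9 MHC class II genes were higher. HLA-DPB1 rose by 2.09 ± 0.42 (adjusted p = 0.00122), though HLA genes share reads with one another. Both lists had an adjusted p of 0.258 with an estimated correlation (camera adjusted p = 2.2e-08 and 1.1e-07). Ribosomal protein genes rose in 19 of 43 members (34 higher adjusted over the list alone), with a mean of 0.57, at 0.54 within batch 2 and 0.62 within batch 4. Their camera adjusted p was 4.7e-14, with 0.336 as the adjusted p with an estimated correlation. The batch 4 levels of ribosomal protein genes were 6.18 log2 CPM in peritumor replicate 4 and 7.01 in replicate 5, against 5.38 to 6.67 in epilepsy. Their batch 4 value thus rests mostly on replicate 5.

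Glycogen metabolism fell, with PYGM, muscle-type glycogen phosphorylase, at -1.80 ± 0.45 (adjusted p = 0.00648) and PPP1R3C, a glycogen targeting subunit, at -1.33 ± 0.35 (adjusted p = 0.0092), while GBE1 was higher, a call lost without peritumor replicate 1, 3, 5 or 6 (adjusted p up to 0.322). Genes of synapse formation and phagocytosis fell in 6 of 15 members, with the phagocytic receptor MERTK at -1.41 ± 0.36 (adjusted p = 0.00691). Cholesterol synthesis, lipid metabolism and metallothioneins fell with means of -0.50, -0.23 and -0.70, and 2, 3 and 0 of their members passed. The means of glycogen metabolism and of synapse formation were -0.54 and -0.36. In the order named, 6, 7, 0, 3 and 0 members of these 5 lists were lower adjusted over the list alone, and 1, 1, 0, 0 and 0 were higher. Their means within batch 2 were -0.39, -0.42, -0.63, -0.40 and -1.32, and within batch 4 they were -0.45, -0.31, -0.14, -0.07 and -0.09. Immediate early genes, reactive astrocyte genes, NF-kB and cytokine genes, cell cycle, glioma-associated genes, microglia and endothelium rose with means of 1.23, 1.05, 1.17, 1.01, 0.78, 0.82 and 0.98. Of their members 2, 3, 2, 3, 5, 1 and 2 passed, and 2, 5, 7, 3, 5, 1 and 2 were higher adjusted over the list alone. Within batch 2 their means were 2.08, 1.10, 1.76, 1.61, 0.91, 0.88 and 0.66, and within batch 4 they were 0.11, 0.39, 0.29, -1.18, -0.32, 0.59 and 1.44. With an estimated correlation, the adjusted p of these 12 lists ran from 0.258 to 0.593. The call was lost for NF-kB and cytokine genes without peritumor replicate 1 (adjusted p = 0.0687), for glioma-associated genes without replicate 2 (adjusted p = 0.0935), and for microglia without replicate 1 or 4 (adjusted p up to 0.332). It was lost for endothelium without replicate 4 or 5 (adjusted p up to 0.111), for lipid metabolism without replicate 3, 4 or 6 (adjusted p up to 0.102) and for metallothioneins without replicate 1, 4 or 6 (adjusted p up to 0.122). Without replicate 1 the means of NF-kB and microglia genes were 0.49 and 0.18, without replicate 6 those of cell cycle and glioma-associated genes were 0.49 and 0.51, and without replicate 5 those of lipid metabolism and metallothioneins were -0.46 and -1.44. Without the 3 libraries that stand apart the calls for cholesterol synthesis (-0.30, adjusted p = 0.106) and lipid metabolism (-0.060, adjusted p = 0.28) were lost, and the means of immediate early genes and endothelium were 0.82 and 1.63. With the mitochondrial rRNA covariate the glioma-associated call was lost (0.17, adjusted p = 0.141), and the means of cell cycle and reactive genes were 0.13 and 0.61. The cell type covariates ended the call for lipid metabolism (adjusted p = 0.0539). Calls of microglia, endothelium and oligodendrocytes say nothing under these covariates, which are their own scores. The other 14 lists did not pass, at adjusted p from 0.0686 to 0.852.

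In all, 2417 genes passed in this comparison, 1253 higher and 1164 lower. The split was 1482 and 991 with RLE scaling, 1707 and 823 without the filter on low counts, 882 and 511 without the libraries that stand apart and 41 and 2 within batch 4. Among the highest were LRP2, an endocytic receptor (ENSG00000081479, chromosome 2, 169127109 to 169362685), at 4.42 ± 0.75 (SE, adjusted p = 0.000276), AZGP1 at 4.11 ± 0.66 (adjusted p = 0.000126) and EYA4 at 4.28 ± 0.58 (adjusted p = 1.5e-05). Among the lowest were FSTL5 at -3.30 ± 0.66 (adjusted p = 0.00111), RGR at -2.62 ± 0.61 (adjusted p = 0.00402) and the somatostatin receptor SSTR2 at -2.22 ± 0.55 (adjusted p = 0.0054). Each of these 6 genes kept its call when any peritumor library was left out. With the cell type covariates the calls of LRP2, GLUL, SLC1A2, MYRF, CLDN11, CNP, PPP1R3C and MERTK were lost (adjusted p from 0.0548 to 0.283), and with the mitochondrial rRNA covariate that of SLC1A2 (-1.25, adjusted p = 0.0638). MYRF, CLDN11 and CNP belong to the oligodendrocyte list, whose score is among the covariates, so their losses under these say nothing. Within batch 4 SLC1A2 had -0.47, KCNJ10 -0.66, AZGP1 2.74 and RGR -1.72. The count was 1385 with mitochondrial rRNA percent as a covariate, 1393 without the 3 libraries that stand apart, 663 with the cell type covariates, 677 within batch 2 and 43 within batch 4. It was 1605, 1604 and 1545 without peritumor replicates 1, 3 and 6. Of 721 genes called within batch 2 among the 17932, 77.7% had the same sign within batch 4, against 61.8% of all genes.

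**Figure D3:**
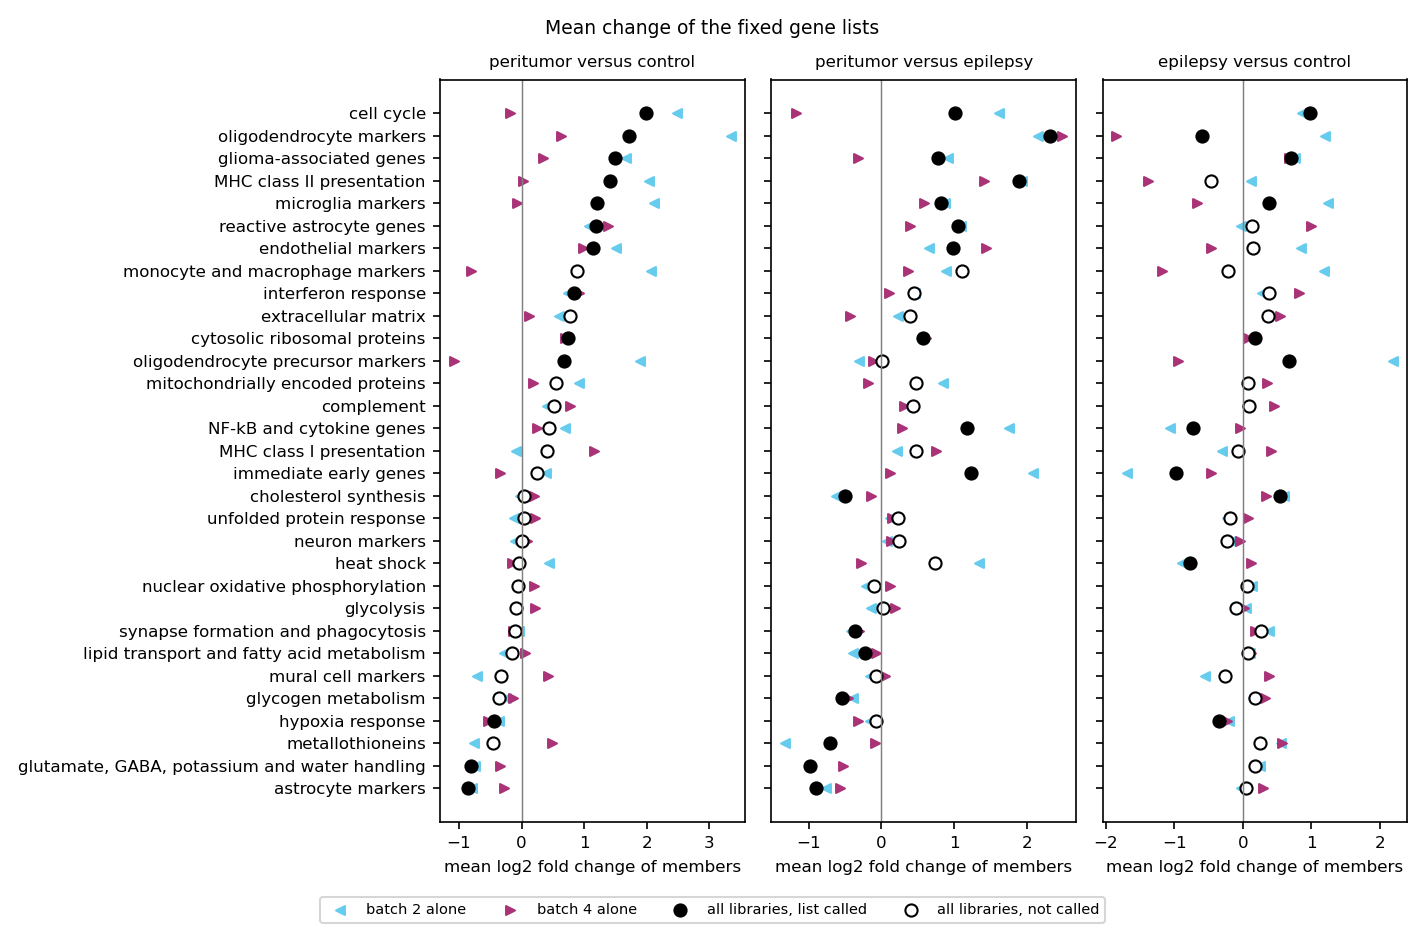
Mean log2 fold change of the members of 31 gene lists in the 3 comparisons, in all libraries (circles, filled where camera's adjusted p was under 0.05 at a preset correlation of 0.01) and in batches 2 and 4 fitted alone (triangles). Ribosomal proteins lie at 0.74 against control and 0.57 against epilepsy, with the batch values beside them, while cell cycle lies below 0 in batch 4 in both peritumor comparisons.

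Between epilepsy and control libraries, 1 gene passed. NPFFR1, a neuropeptide FF receptor (ENSG00000148734, chromosome 10, 70247329 to 70283676), was lower in epilepsy at -2.90 ± 0.53 (SE, adjusted p = 0.0363), from 18.5 ± 15.6 CPM in control (SD, n = 12) to 2.35 ± 2.75 CPM in epilepsy (SD, n = 31). It had -3.10 within batch 2 and -2.25 within batch 4. Its call was lost without any 1 of control replicates 3, 4, 5, 6, 7, 9 and 12, which left 0 genes each. In edgeR 1945 genes had an unadjusted p under 0.05, where 896.6 are expected by chance, and DESeq2 called 131 genes and limma voom 79. The count was 6 without control replicate 10 and 79 without control replicate 11, and 0 with either set of covariates. AQP4 had a log2 fold change of 0.09 ± 0.22 (adjusted p = 0.924), GFAP 0.33 ± 0.38 (adjusted p = 0.802) and SLC1A2 0.04 ± 0.33 (adjusted p = 0.979). The genes of smallest p after NPFFR1 included KLF4, PARP8, TRAM1, SLC20A1 and HIST1H1E, each at an adjusted p of 0.126.

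As lists, cholesterol synthesis rose in epilepsy with a mean of 0.54 (camera adjusted p = 2.1e-09), at 0.60 within batch 2 and 0.34 within batch 4. Its adjusted p was 0.4935 with an estimated correlation, and fry called no list in this comparison. No member passed over all genes, and 11 of 20 were higher adjusted over the list alone. SQLE, squalene epoxidase, had 0.75 ± 0.23 (adjusted p = 0.221), and 28 of 31 epilepsy libraries lay above the control median. Heat shock genes, immediate early genes, NF-kB and cytokine genes and hypoxia genes fell, with means of -0.77, -0.98, -0.73 and -0.36. Within batch 4 these means were 0.12, -0.47, -0.04 and -0.23, against -0.90, -1.69, -1.06 and -0.21 within batch 2. As differences of the mean log2 CPM of libraries they were -0.17, -0.86, -0.73 and -0.46 within batch 4, so the measures disagreed there for heat shock and NF-kB genes. Ribosomal proteins, cell cycle and glioma-associated genes rose with means of 0.17, 0.98 and 0.71, at 0.18, 0.86 and 0.76 within batch 2 and 0.08, 0.99 and 0.67 within batch 4. As differences of the mean log2 CPM of libraries they were 0.26, 0.33 and 0.70 within batch 2 but 0.011, 0.037 and -0.13 within batch 4, so batch 4 did not repeat these rises by that measure. Oligodendrocyte markers fell (-0.60) while precursor and microglia markers rose (0.68 and 0.38), but all 3 went opposite ways in the batches. Their means were 1.19, 2.19 and 1.24 within batch 2 and -1.85, -0.95 and -0.67 within batch 4. No member of these 11 lists passed over all genes. Adjusted over the list alone, 4 heat shock, 1 immediate early, 2 NF-kB and cytokine and 2 hypoxia genes were lower, and no member of the last 6 lists passed. The adjusted p of the 11 lists was at least 0.4935 and at most 0.805 with an estimated correlation. The cell cycle call was lost without control replicate 12 (adjusted p = 0.0616), the microglia call without control replicate 2, 4 or 6 (adjusted p up to 0.091) and the oligodendrocyte call without control replicate 9, 10, 11 or 12 (adjusted p up to 0.27). Without the libraries that stand apart the means of cell cycle and glioma-associated genes were 0.38 and 0.33. With the mitochondrial rRNA covariate they were 0.58 and 0.35, and the glioma-associated call was lost (adjusted p = 0.0544). The cell type covariates ended the call for hypoxia (adjusted p = 0.0545), while microglia and oligodendrocytes cannot be judged under their own scores. Leaving out 1 control library moved NF-kB and immediate early genes to -0.46 and -0.58 (replicate 6), ribosomal proteins to 0.28 (replicate 1) and heat shock to -0.43 (replicate 12). It moved microglia, precursors and oligodendrocytes to 0.62, 1.02 and -0.26 (replicate 10). The other 20 lists did not pass, at adjusted p from 0.0555 to 0.904.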

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

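Within the 6 peritumor libraries, 142 measures (31 list levels, 108 named genes and 3 library measures) were searched for a library whose gap to its nearest neighbour exceeded the 95% limit of Dixon's test, as a share of the group's range. Of these, 11 were found where chance gives about 7.1, so a single one can be due to chance. The tests below on cell type scores, on the libraries that stand apart and on mitochondrial rRNA with cell cycle genes were chosen after the results were seen. The demand that an effect across libraries exceed its SE by a factor of 2 was also added then. The mitochondrial rRNA covariate itself was also chosen after the data were seen. What the tests on matched genes, on that covariate with ribosomal proteins and on precursors would show was written before they were run, but after the patterns were seen.

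Peritumor replicate 6 was low for the glycogen targeting subunit PPP1R3C, at 2.48 log2 CPM against 5.98 to 6.79 in the others (gap 0.813 of the range), and for the glycogen metabolism list, at 4.15 against 5.10 to 5.66 (0.63). Replicate 3 was high for NLGN1 (6.84 against 5.21 to 5.62, 0.748) and HSPB1 (8.72 against 4.95 to 6.05, 0.707), and low for the microglia genes C1QB (2.22 against 4.59 to 5.75, 0.672) and CD14 (-0.61 against 3.63 to 5.50, 0.694). Replicate 5 was low for CSPG4 (0.86 against 5.02 to 6.67, 0.715), MCAM (0.95 against 3.61 to 5.01, 0.656) and PIEZO2 (-2.44 against 3.19 to 5.25, 0.733), and high for RPL30 (7.98 against 6.88 to 7.29, 0.627) and the glycolysis list (7.33 against 6.09 to 6.52, 0.654).

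Other splits of the same libraries into groups of the same sizes were counted, 100 per comparison with the real one included. For peritumor against control, 1 split, the real one with 1480 genes, gave as many, and the highest other gave 605. For peritumor against epilepsy it was again 1, the real one with 2417 genes, and the highest other gave 626. These splits were drawn across batches, with batch as a term of each fit. In a further 100 splits per comparison, chosen after the results were seen and drawn within each batch, the real count was again reached by 1 split each, the real one, and the highest others gave 100 and 855. A random split of these libraries is thus an unlikely source of these 2 counts, though 100 splits cannot show a share under 1 in 100. The splits treat libraries as independent, which the labels do not show. Other splits also called genes (46 and 58 of those across batches, 33 and 53 of those within), and since they hold part of the group difference their cause is not known. For epilepsy against control, 28 of 100 splits gave as many genes as the real 1, and the highest other gave 159 (23 splits and 149 within batches), so chance cannot be excluded for that count.

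The first pattern is the lower level of astrocyte markers in peritumor than in control libraries (mean log2 change -0.85). A lower share of astrocytes, with the mix of other cells unchanged, would raise every other cell type alike. The oligodendrocyte score rose over the neuron score by 1.79 ± 0.77 on the log2 scale (SE), which argues against that form as the whole cause. This test cannot judge a lower share with more oligodendrocytes in place of astrocytes. In batch 4 the oligodendrocyte score was 8.72 and 4.33 in the peritumor libraries, against 6.64 to 7.76 in control. With the 4 cell type scores as covariates, that of oligodendrocytes among them, the change was -0.952 and so did not shrink. Without the libraries that stand apart it was -0.523, so these libraries do not account for all of it. Across libraries it was -1.17 ± 0.34 (SE), and -0.56 ± 0.22 without them. A linear term in a log score may miss dilution where the RNA of other cells is high. In peritumor replicate 1 oligodendrocyte markers averaged 9.39 log2 CPM, against 9.20 for astrocyte markers. More oligodendrocyte RNA thus cannot be excluded as a part of the change, and precursor markers were not among the 4 scores. A change within astrocytes around tumours may contribute and stays open.

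The second pattern is the higher level of ribosomal protein genes in peritumor libraries (0.74, and 0.75 ± 0.19 across libraries, SE). Genes matched on transcript length, GC content and expression had a mean of 0.14, at most 0.43 in any of 1000 matched lists, and the difference was 0.602. Length here was that of the longest annotated transcript, with a median of 1962 bases for the ribosomal protein genes. The transcripts expressed may be shorter, so this match cannot judge a bias toward short transcripts. With mitochondrial rRNA percent as a covariate the change was 0.563 (0.57 ± 0.19 across libraries, SE), and with the 4 cell type scores it was 0.696. Neither is thus likely to be the whole cause. Sharing of reads with pseudogenes was not tested, and a biological difference of the tissue stays open as a hypothesis.

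The third pattern is the higher level of cell cycle genes (1.42 ± 0.44 across libraries, SE). Its mean log2 change was 2.00, and -0.19 within batch 4. Without the libraries that stand apart it was 1.2 (0.99 ± 0.36 across libraries, SE), and with the precursor score as a covariate it was 2.0 (1.23 ± 0.45), so neither accounts for it alone. With mitochondrial rRNA percent as a covariate it fell to 0.712 and stayed called (1.11 ± 0.47 across libraries, SE). The value across libraries thus fell less than the mean log2 change did. The mean share of mitochondrial rRNA was higher in these peritumor than in these control libraries (adjusted p = 0.218 in the exact permutation test). Its part and that of the tissue thus cannot be told apart. Dividing cells around tumours may also contribute, and this was not tested.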

How the results depend on the processing

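No paired analysis was possible because the replicate numbers were given in accession order and only name the samples. The libraries that stand apart and the mitochondrial rRNA covariate were chosen after seeing the data, and the other alternatives before. The count of genes in peritumor against control was 1480. It was 829 without the filter on low counts, 670 with only the groups compared, 661 with the cell type covariates, 521 without the 3 libraries that stand apart, 56 with the mitochondrial rRNA covariate and 0 within batch 4, where 2 peritumor and 3 control libraries were compared. Leaving out 1 library gave 375 (without peritumor replicate 3) to 1995 (without peritumor replicate 5), and 860 without peritumor replicate 1. RLE scaling gave 1529, no batch term 1493, DESeq2 2213 and limma voom 1659. The count in epilepsy against control was 1. It was 7 without the filter, 463 without the batch term, 3 with only the groups compared, 22 within batch 2, 131 with DESeq2, 79 with limma voom, 5 without the libraries that stand apart, and 0 with the cell type covariates and with the mitochondrial rRNA covariate. Leaving out 1 control library gave 0 to 79, with 0 without replicate 3, 4, 5, 6, 7, 9 or 12, 6 without replicate 10 and 79 without replicate 11. The count in peritumor against epilepsy was 2417. It was 677 within batch 2, 43 within batch 4, 663 with the cell type covariates, 1385 with the mitochondrial rRNA covariate and 1393 without the libraries that stand apart. Leaving out 1 peritumor library gave 1545 (replicate 6) to 2983 (replicate 5), with 1605 without replicate 1 and 1604 without replicate 3. The lists called were 13, 11 and 17 in the order peritumor against control, epilepsy against control and peritumor against epilepsy. With an estimated correlation they were 0 in each, fry gave 0 for epilepsy against control, and 8 were called within batch 4 for peritumor against epilepsy. Leaving out 1 library gave 12 to 20 lists for peritumor against control, with 20 without peritumor replicate 5. The cause of these moves was not tested, except that fewer libraries entered the fits within a batch.

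Of the 42 named genes called in peritumor against control, 11 kept the call in all 18 leave-one-out fits, 16 without the libraries that stand apart, 26 with the cell type covariates and 4 with the mitochondrial rRNA covariate (CDK4, EYA4, PAPLN and TGFBI). Of the 65 in peritumor against epilepsy, 37 kept it in all 6 leave-one-out fits, 49 without the libraries that stand apart, 29 with the cell type covariates and 49 with the mitochondrial rRNA covariate. Some named genes, such as CNP in both comparisons, are part of the scores used as cell type covariates. The numbers kept under these covariates are thus partly fixed by that. 

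In epilepsy against control, without the batch term, values that turned sign were SLC1A2 (-0.0050). Without the batch term, peritumor against epilepsy had opposite signs for ALDH1L1 (0.16), P2RY12 (-0.051). Signs of epilepsy against control turned with only the groups compared for SNAP25 (-0.046). In peritumor against control, within batch 2, values that turned sign were ALDH1L1 (0.39). Within batch 2, epilepsy against control had opposite signs for the list of oligodendrocyte markers (1.19), MAG (1.31), SLC1A2 (-0.017), SNAP25 (-0.11), ENPP2 (1.76), AQP4 (-0.12), OPALIN (0.91). Signs of epilepsy against control turned within batch 2 for MBP (0.25). In peritumor against epilepsy, within batch 2, values that turned sign were ALDH1L1 (0.79). Within batch 4, peritumor against control had opposite signs for the list of microglia markers (-0.051), the list of oligodendrocyte markers (0.65), the list of oligodendrocyte precursor markers (-1.06), DLL3 (-0.34), TREM2 (-0.19), TOP2A (-1.41), SNAP25 (-0.057). Signs of peritumor against control turned within batch 4 for C1QC (-0.14), AQP4 (0.33), CSPG4 (-1.33), OLIG1 (-0.61), OLIG2 (-0.60), HLA-DPB1 (-0.21). In epilepsy against control, within batch 4, values that turned sign were the list of heat shock (0.13), the list of glioma-associated genes (0.75), the list of microglia markers (-0.66), the list of oligodendrocyte precursor markers (-0.95), TYROBP (-0.49), NFKB2 (0.21), CXCL2 (2.18). Within batch 4, epilepsy against control had opposite signs for HSPB1 (0.24), HSPE1 (0.24), PDGFRA (-0.51), ALDH1L1 (0.29), P2RY12 (-0.67), CSPG4 (-0.76), LHFPL3 (-1.0). Signs of epilepsy against control turned within batch 4 for AIF1 (-0.38). In peritumor against epilepsy, within batch 4, values that turned sign were the list of cell cycle (-1.14), the list of immediate early genes (0.12), MCM5 (-0.018), HSPB1 (-0.24), SNAP25 (-0.13), CLDN5 (0.83). With the cell type covariates, peritumor against control had opposite signs for ITM2A (-0.0042), P2RY12 (-0.60). Signs of epilepsy against control turned with the cell type covariates for the list of oligodendrocyte markers (0.054), MAG (0.080), SLC1A2 (-0.052), MBP (0.35). In peritumor against epilepsy, with the cell type covariates, values that turned sign were NDRG1 (-0.12), P2RY12 (-0.80), CLDN5 (0.029), MBP (-0.13). With limma voom, peritumor against control had opposite signs for SNAP25 (-0.27). Signs of peritumor against epilepsy turned with limma voom for SNAP25 (-0.41). In peritumor against control, without the 3 libraries that stand apart, values that turned sign were SNAP25 (-0.37). Without the 3 libraries that stand apart, epilepsy against control had opposite signs for SNAP25 (-0.024), MBP (0.012). Signs of peritumor against epilepsy turned without the 3 libraries that stand apart for SNAP25 (-0.35), CLDN5 (0.19). In peritumor against epilepsy, with the mitochondrial rRNA covariate, values that turned sign were SNAP25 (-0.010), ALDH1L1 (0.0055), CLDN5 (0.34). Leaving out 1 library turned the sign of genes that were not called. In peritumor against control these ranges were -0.62 to 0.55 for SNAP25, -0.034 to 1.72 for MBP. In epilepsy against control these ranges were -0.045 to 0.096 for SLC1A2, -0.024 to 0.17 for SNAP25, -0.31 to 0.0049 for ALDH1L1, -0.14 to 0.27 for MBP. In peritumor against epilepsy these ranges were -0.57 to 0.52 for SNAP25, -0.35 to 0.17 for ALDH1L1, -0.43 to 0.45 for P2RY12, -1.17 to 0.031 for CLDN5. Of the lists, only those called are named above, where the direction of the camera test turned, which can happen while the mean log2 change keeps its sign, since camera compares a list with other genes. The mean alone turned within batch 4 for cell cycle in peritumor against control (-0.15) and glioma-associated genes in peritumor against epilepsy (-0.52). It also turned with the cell type covariates for endothelial markers in peritumor against control (-0.060) and against epilepsy (-0.14), and without the batch term for NF-kB and cytokine genes in epilepsy against control (0.014). Oligodendrocyte, microglia and endothelial markers are part of the cell type covariates, so their turns under these say nothing. Means of lists that were not called turned within a batch as well, such as monocyte and macrophage markers in peritumor against control (-0.81 within batch 4) and epilepsy against control (1.19 within batch 2), metallothioneins in peritumor against control (0.49 within batch 4) and extracellular matrix in peritumor against epilepsy (-0.43 within batch 4). The cause of these turns was not tested. The median depth was 5334710 counts in batch 2 and 17057400 in batch 4, and what depth limits was not tested apart from the number of libraries.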

Other observations

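All tests in this part were chosen after the results were seen. Across epilepsy and control libraries, the level of several cell type lists depended on the sequencing batch in a way that differed between the groups. Monocyte and macrophage markers were higher in epilepsy by 1.11 on the log2 scale within batch 2 and lower (-1.36) within batch 4. Oligodendrocyte precursor markers had 1.85 and -1.32, oligodendrocyte markers 0.69 and -2.42, and microglia markers 1.49 and -1.29. In a permutation test of the difference between the batches, with labels permuted within each batch, these 4 of 31 lists had adjusted p values of 0.0287, 0.0287, 0.0407 and 0.0474. Endothelial markers, at 0.83 and -0.92, had an adjusted p of 0.12. Batch 4 held 3 control libraries, so its values rest on few.

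Immediate early genes, which neurons and glia induce within minutes of stimulation, and heat shock genes varied together over the 49 libraries. Pearson's r was 0.513 (permutation p = 0.00015) and Spearman's rho 0.531 (permutation p = 0.00017). It was 0.498 without the 2 libraries farthest from the median of the immediate early genes. Within batch 2 r was 0.691 (permutation p = 0.00125) and within batch 4 it was 0.575 (permutation p = 0.00542), and after removal of the mean of each group in each batch it was 0.539. The permutations over 49 libraries pooled the groups and batches, and those within a batch pooled the groups, here and in the relations below. Cell cycle and oligodendrocyte precursor genes had r = 0.491 (permutation p = 0.00035) and rho = 0.604 (permutation p = 2e-05), and r = 0.576 without the 2 farthest libraries. That relation did not hold within batch 4 (r = 0.043, permutation p = 0.873), against r = 0.54 within batch 2 (permutation p = 0.0155), and after removal of those means r was 0.183. Astrocyte and oligodendrocyte markers had r = -0.159 (permutation p = 0.277) and rho = -0.369 (permutation p = 0.00949), with r = -0.44 without the 2 farthest libraries, -0.544 within batch 2, -0.10 within batch 4 and -0.069 after removal of those means. Astrocyte and microglia markers had r = -0.17 (permutation p = 0.246) and rho = -0.452 (permutation p = 0.00109), with r = -0.406 without the 2 farthest, -0.088 within batch 2, 0.0017 within batch 4 and 0.046 after removal of those means. These were the 4 relations computed, and the adjusted Pearson p values were 0.0006, 0.0007, 0.277 and 0.277 in the order given.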
